A study of Mus musculus with 2 samples.

How the data were processed

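Liver RNA of 2 pools was compared, 1 from male wild-type mice after renal ischaemia-reperfusion and 1 from mice after sham surgery, each pool with liver of 3 mice. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was prepared from 6 ug of it by the Affymetrix protocol. The deposited values are a microarray intensity for each probe set on a linear scale, with 1 decimal. The software that summarised probes into probe sets and the version of it are not given in the sources used here. A trimmed mean of the deposited intensity values, leaving out 2% at each end, was 500.0 on both arrays, so the values had been scaled to a common target before deposit. Whether the authors subtracted background or filtered probes is not given in the sources used here. Both groups come from the treatment label of each sample. All deposited columns of per-sample values were used.

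Of the probe sets, 64 are controls and 45037 are not. Gene names came from a table of the array platform's annotation, which can be old, and 34945 probe sets had 1 gene, 932 several genes and 9160 none, the last being unnamed here. For 34754 of the probe sets with 1 gene, the symbol was updated through the Entrez ID, and the older symbol was kept for the others. Probe sets with several genes or none named no gene. No genome build applies to these probe sets, so no coordinates are given.

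Values were taken as log2 of the signal plus a pseudocount of 16, which reduces the differences of dim probe sets. All folds are on this scale. A probe set entered when the brighter of its 2 signals was at or above the median of that array over probe sets that are not controls, which left 21003 probe sets. Each gene was represented by the probe set with the highest mean log2 value, which gave 13117 genes, 10923 of them at or above the median on both arrays and 2194 on 1 array. Differences are the renal ischaemia-reperfusion pool minus the sham pool. Their median over genes was -0.01 and their quartiles -0.45 and 0.42, and the log2 signals of the arrays had a Pearson correlation of 0.79 across genes, which are not independent replicates. The number of arrays limits the precision, and with 1 array per group the spread between mice is unknown, so no test was run and genes were counted by a 2-fold threshold.

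Gene lists were described by the median log2 difference of their members and its percentile among 10000 random lists of the same size, drawn to match the members in 20 bins of mean log2 value. A list was said to lie outside the random range under a percentile of 2.5 or over 97.5, and needed at least 5 members. A percentile describes these 2 arrays and does not test the conditions. The main settings, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

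Genes were named by a rule. It took the 12 highest and 12 lowest differences among genes at or above the array median on both arrays, and the 5 highest and 5 lowest among genes at or above it on 1 array only. Genes without a proper symbol, and genes whose filtered probe sets differed in sign, were passed over. The rule also took up to 2 highest and 2 lowest members of each list and a panel of 16 genes given whatever their values. For a gene under the median on 1 array, the bound on the fold is the brighter signal against the median of the dim array, each with the pseudocount. List medians use the measured differences of all members. Probe sets with the suffix _x_at or _s_at can cross-hybridise, and values from them are uncertain.

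The alternatives were log2 differences centred on their median, removal of a loess trend on signal (span 0.3), quantile normalization, pseudocounts of 1 and 64, no filter, a filter at the 75th percentile, the mean of a gene's probe sets or the probe set with the smallest difference, probe sets with the suffix _x_at, _s_at or _a_at left out, thresholds of 1.5-fold and 3-fold, random lists without matching, and lists without members of other lists. Chosen after the data were seen were the hybridisation controls as the reference, a filter that asks both arrays to be at or above their medians, and signals under the array median raised to that median. Probe sets with the suffix _a_at match several transcripts of 1 gene, and they were left out in the alternative on suffixes as fixed in advance, though they are not called cross-hybridising here.

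The steps were tested on simulated arrays with a noise SD of 0.3 per array and 12661 genes. All 50 genes simulated at a log2 difference of 2.0 and all 50 at -2.0 were called at 2-fold, as were 45 of 50 at 1.5 and 43 of 50 at -1.5. Of 12233 genes simulated without a difference, 252 (2.06%) were called. The noise was a chosen setting, whereas probe sets of the same gene on the real arrays disagreed with an SD of 0.72 in log2 difference. These shares check the steps and do not give the error of the 2-fold calls on the real arrays. A list shifted by 0.6 was estimated at 0.69, and 7% of 200 lists without a shift lay outside the random range. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.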

Results

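Affymetrix arrays were used to measure liver transcripts in male wild-type C57BL/6 mice, 8 weeks old, whose kidneys had been injured. One group of 3 mice had 30 minutes of warm ischaemia of both kidneys followed by reperfusion, and the other group of 3 mice had a sham operation. Livers were taken 24 hours after surgery, and 100 mg of frozen liver from the 3 mice of a group was combined into 1 pool. Each pool was hybridised to 1 array, so there were 2 samples and no replicates. No replicate error, test or p-value could therefore be given, and every difference describes these 2 pools. The median signal of probe sets that are not controls was 257.0 in the sham pool and 254.1 in the renal ischaemia-reperfusion pool. The ratio of 3' to 5' control signal was 1.38 and 1.24 for beta-actin and 0.744 and 0.721 for Gapdh, in the same order.

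The comparison addressed how injury of the kidneys alters transcripts in the liver, an organ that was not itself made ischaemic. In the renal ischaemia-reperfusion pool, transcripts of acute phase proteins, of the metallothioneins Mt1 and Mt2 and of the unfolded protein response in the endoplasmic reticulum were higher than in the sham pool. Transcripts of hepatocyte transporters and of enzymes of drug metabolism, fatty acid and cholesterol synthesis, amino acid catabolism and nicotinamide metabolism were lower. Among the largest differences were those of Lcn2, which encodes lipocalin 2 and was at least 189-fold higher, and of Hsd3b5, a steroid dehydrogenase of male mouse liver, which was at least 21.2-fold lower. Of 13117 genes, 1143 (8.71%) had a signal at least 2-fold higher after renal ischaemia-reperfusion and 1258 (9.59%) a signal at least 2-fold lower. Probe sets of the same gene disagreed with an SD of 0.72 in log2 difference, against a 2-fold threshold of 1 on that scale. How many of the 2-fold differences exceed such disagreement is therefore unknown.

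**Figure D1:**
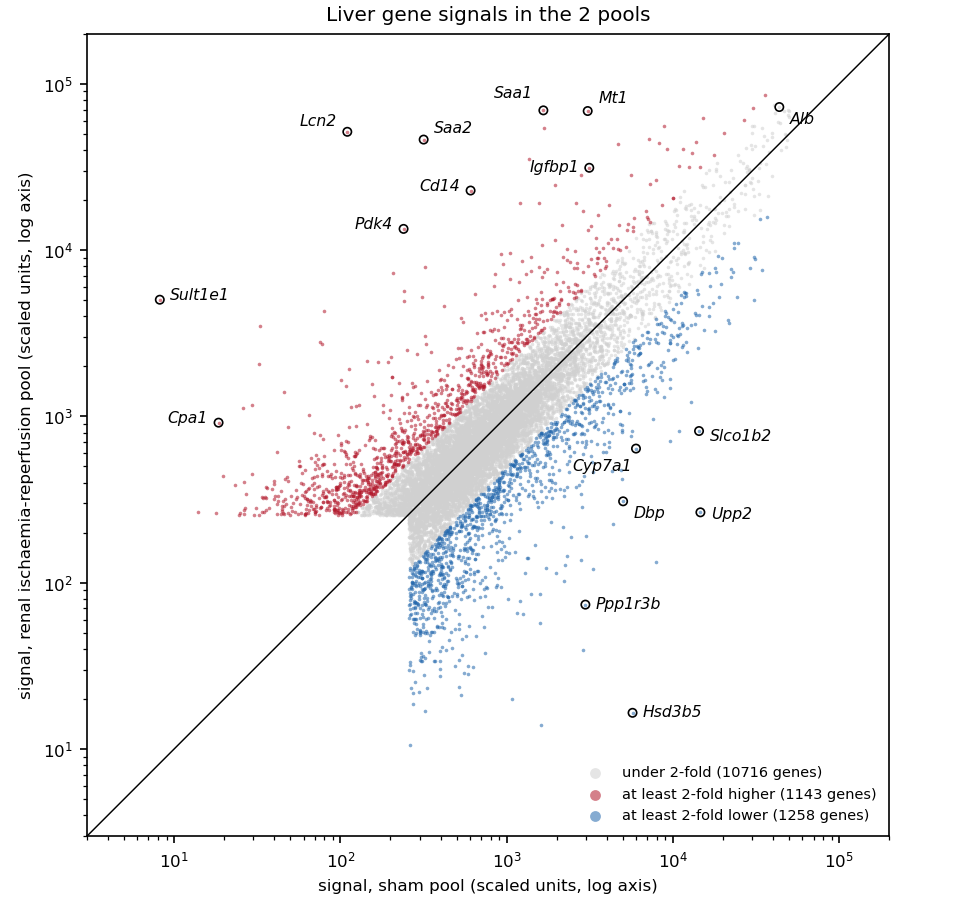
Signal of each gene in the sham pool (horizontal, scaled units, log axis) and in the renal ischaemia-reperfusion pool (vertical, scaled units, log axis), 1 point per gene and 1 array per pool. Red points are the 1143 genes at least 2-fold higher, blue points the 1258 genes at least 2-fold lower, and the line marks equal signals. Lcn2, Saa1, Saa2 and Mt1 lie far above the line, and Hsd3b5, Upp2 and Slco1b2 far below it.

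At least 4-fold differences were seen for 271 genes that were higher and 323 that were lower, and at least 8-fold differences for 61 and 68 genes. Among genes at or above the array median on both arrays, 561 were at least 2-fold higher and 674 at least 2-fold lower. With signals under the array median raised to that median, 721 of all genes were at least 2-fold higher and 864 at least 2-fold lower. The split depended on the reference. The 18 probe sets for bacterial hybridisation controls were all higher on the renal ischaemia-reperfusion array, with a median log2 difference of 0.28. With these controls as the reference, which shifts every log2 difference by -0.28, 756 genes were at least 2-fold higher and 2016 at least 2-fold lower, so the higher genes made up 27.3% instead of 47.6% of them.

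Among genes at or above the median on both arrays, Saa2 and Saa1 led the higher side. They encode serum amyloid A, a plasma protein made by hepatocytes in inflammation. Saa1 had a signal of 1661 in the sham pool and 69230 in the renal ischaemia-reperfusion pool, 41.3-fold higher. Saa2 went from 316.5 to 46200 by a probe set that can cross-hybridise with related genes, so its 139-fold difference is uncertain. Cd14, the lipopolysaccharide co-receptor, went from 606.4 to 22816 (36.7-fold). Mt2, a metallothionein that binds zinc, went from 1672 to 54347 (32.2-fold). Nid1, a basement membrane protein, was 16.1-fold higher, Mrap, an accessory protein of the corticotropin receptor, 15.7-fold, and Tgm2, transglutaminase 2, 12.4-fold, all 6 of its probe sets past the filter having the same sign. Apoa4 (25.7-fold), Tubb2a (23.4-fold), Mt1 (22.2-fold), Actg1 (12.2-fold) and Plscr1 (10.5-fold) were also higher, each by a probe set that can cross-hybridise.

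A further 5 genes had a sham signal under the array median, so their fold is given as a lower bound against that median. Lcn2 had a signal of 110.0 in the sham pool and 51458 in the renal ischaemia-reperfusion pool, at least 189-fold higher. Pdk4, a kinase that restrains pyruvate dehydrogenase, was at least 49.2-fold higher, with signals of 239.7 and 13414. Sult1e1, the oestrogen sulphotransferase, had signals of 8.2 and 5031 (at least 18.5-fold). Cidec, a lipid droplet protein, was at least 15.8-fold higher and Rab30, a small GTPase, at least 12.9-fold higher.

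On the lower side, Upp2, a uridine phosphorylase, had a signal of 14612 in the sham pool and 264.9 in the renal ischaemia-reperfusion pool, a 52.1-fold difference by a probe set that can cross-hybridise. Slco1b2, which takes up organic anions into hepatocytes, was 17.2-fold lower (14339 against 816.7), with all 5 probe sets past the filter lower. Dbp, a transcription factor driven by the circadian clock, was 15.5-fold lower. Slc2a2, the main glucose transporter of hepatocytes, was 13.2-fold lower, with signals of 10934 and 812.6. The aldehyde oxidase Aox3 was 10.5-fold lower, and Acss2, which makes acetyl-CoA from acetate, 9.93-fold lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 9.15-fold lower (5989 against 640.4), and Idi1, an enzyme of cholesterol synthesis, 8.88-fold lower. Keg1 (13.2-fold), Car8 (9.46-fold) and Dhrs3 (7.84-fold) were also lower, as was Hes6 (11.4-fold), whose probe set can cross-hybridise.

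The 5 genes with the largest differences among those whose signal was under the array median after renal ischaemia-reperfusion were Hsd3b5, Fam47e, Akr1c14, Pbld1 and Ppp1r3b. Hsd3b5 had signals of 5710.0 in the sham pool and 16.5 in the renal ischaemia-reperfusion pool. Akr1c14, an aldo-keto reductase, was at least 29.4-fold lower, with signals of 7930 and 134.0. Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1, was at least 11.1-fold lower, with signals of 2972 and 73.8. Pbld1 was at least 10.8-fold lower and Fam47e at least 6.03-fold lower.

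**Figure D2:**
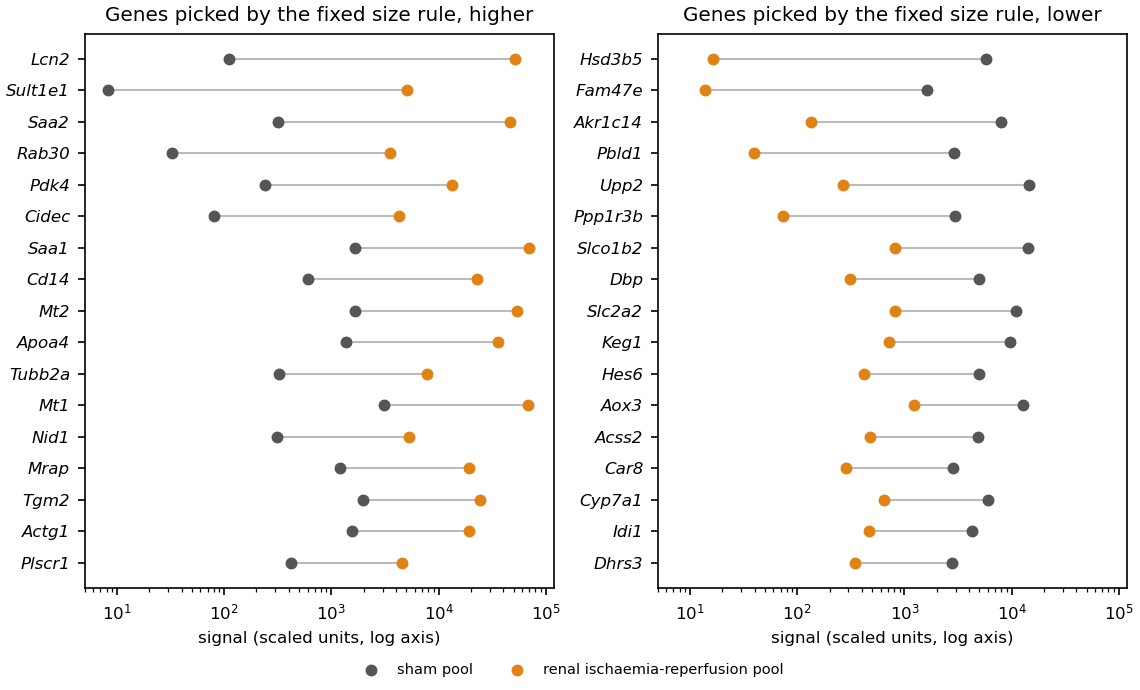
Signals (scaled units, log axis) of the genes picked by the fixed size rule, with the sham pool in grey and the renal ischaemia-reperfusion pool in orange, 1 array per pool. The left panel shows the genes that were higher, from Lcn2 to Plscr1, and the right panel those that were lower, from Hsd3b5 to Dhrs3.

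Several genes of a panel fixed in advance differed little. Cyp3a11, a major drug metabolising cytochrome P450, had signals of 44577 and 39791 (log2 difference -0.16), and Fgf21, a fasting hormone, 768.9 and 818.0 (0.09). Igf1, the hormone induced by growth hormone, had a log2 difference of 0.21 by its brightest probe set, and its 4 probe sets differed in sign. Haptoglobin (Hp, 1.18), hepcidin (Hamp, 0.76), albumin (Alb, 0.73), haem oxygenase 1 (Hmox1, 0.83) and Per1 (0.94) were higher on the log2 scale, and Pck1, the key enzyme of gluconeogenesis, was lower (-1.19). Alb, Hamp and Cyp3a11 had signals near the top of the scale, where the arrays differed (highest signals 55427 sham and 85966 renal ischaemia-reperfusion). By quantile normalization, the similarly bright Gstp1 went from 0.03 to -0.47 and Mgst1 from 0.41 to -0.06. Small differences of such bright genes therefore depend on the scaling. Cdkn1a, the cyclin-dependent kinase inhibitor p21, went from 648.4 to 5476, a log2 difference of 3.05. The cytokines Il6 (127.6 and 165.4) and Tnf (60.6 and 106.4) had signals under the array median in both pools, so no fold is given.

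Where 1 signal of a gene was under the array median, its difference below is given as a bound against that median, and its place in its list is uncertain. Counts of members at 2-fold use the measured signals, and counts with signals under the array median raised to it follow where they change a list outside the random range. The central 95% of random lists matched on signal set the range. Of 48 gene lists fixed in advance, 10 had a median log2 difference above it and 15 a median below it. By chance 2.4 would be outside if genes varied independently, but members of a list can move together. Acute phase proteins were higher. Of the 26 measured members of this list, 17 were at least 2-fold higher and 2 at least 2-fold lower, with a median log2 difference of 1.30, above all 10000 random lists. Its lowest members were Saa4 (-2.09) and Crp (-1.77). Genes of STAT3 signalling and SOCS feedback had a median of 0.89 over 16 genes, 7 of them at least 2-fold higher (6 with dim signals raised) and none 2-fold lower, also above all 10000 random lists. By the probe set with the smallest difference, the median was 0.38, still above the range. Il1r1 (at least 18.3-fold higher) and Junb (at least 7.93-fold) were its highest members, and Cish (-0.78) its lowest. Negative acute phase proteins, which livers usually make less of in inflammation, had a median of 0.37 over 8 genes, inside the random range. Apoa4 (4.68) and Alb (0.73) were the highest of these, and Serpina6 (-0.80), the corticosteroid-binding globulin, the lowest.

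The list of NF-kB targets, cytokines and chemokines lay inside the random range (median 0.04, 19 genes), although Cd14 (5.20) and the chemokine Cxcl1 (3.19) were far higher. Cxcl1 was read by a probe set that can cross-hybridise, and its 3 probe sets ranged from 1.77 to 5.15. Il18 (-1.25) and Il1b (-0.92) were its lowest members. Interferon stimulated genes were lower as a list (median -0.55, 20 genes, percentile 0.15), with 4 members at least 2-fold lower and 2 at least 2-fold higher. With dim signals raised, these were 1 and 1, and the median was -0.35, still below the range. Irf9 (at least 1.80-fold lower) and Gbp6 (at least 1.15-fold) were the lowest, and Iigp1 (1.54) the highest. Complement and coagulation genes were lower too (median -0.47, 28 genes, percentile 0.52), with 6 members at least 2-fold lower and none 2-fold higher. Serpind1, heparin cofactor II, was the lowest of them (-2.51), and F13b stood at -1.81.

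Genes of the unfolded protein response in the endoplasmic reticulum had a median of 1.09 over 23 genes, above all 10000 random lists, with 13 members at least 2-fold higher and none 2-fold lower. The median was 0.55 by the probe set with the smallest difference, still above the range. Creld2 (928.4 to 9469, log2 difference 3.33) and Manf (2621 to 19321, 2.87) were the highest, while Atf3 (-0.37) and Trib3 (0.02) differed little. Heat shock genes lay inside the random range (median -0.15, 14 genes). The inducible Hspa1b (-2.70) and Hspa1a (at least 1.28-fold lower) were their lowest members, and Hsp90aa1 (0.79) the highest. Heat shock genes were below the range by the mean of each gene's probe sets (-0.65). Ribosomal protein genes had a median of 0.74 over 23 genes (percentile 99.9; 0.49 by the smallest difference), although only 3 were at least 2-fold higher. Rps19 (1.27) was the highest and Rps6 (-0.17) the lowest. In the same pool, pancreatic acinar markers had a median of 1.58.

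Targets of p53 and genes of growth arrest and apoptosis had a median of 0.64 over 20 genes (percentile 99.99), with 8 at least 2-fold higher (5 with dim signals raised) and none 2-fold lower. Cdkn1a (3.05) and Gadd45g (2.26) led this list, and Bbc3 (-0.60) was its lowest member. Cell cycle genes lay inside the range (median -0.14, 17 genes), from Mcm3 (at least 1.52-fold higher) to the thymidine kinase Tk1 (at least 2.51-fold lower). The other probe set of Mcm3 went the other way, with dim signals of 280.1 in the sham pool and 180.0 in the renal ischaemia-reperfusion pool. Glucocorticoid responsive genes were higher (median 0.94, 21 genes, above all 10000 random lists), with Lcn2 and Sult1e1 highest and 3 members at least 2-fold lower. Of its members, Lpin1 (-2.67) and Tsc22d3 (-2.25), the glucocorticoid-induced leucine zipper, were the lowest. 13 members of this list stand in other lists, and the 8 that do not had a median of 0.17, inside the random range. With both arrays at or above their medians, the list stood at 0.61. Metallothioneins with zinc and iron genes had a median of 0.55 over 21 genes (percentile 99.9), with Mt2 and Mt1 at 5.01 and 4.48 and the iron exporter Slc40a1 at -1.86. This list lay inside the range in 4 alternatives, at 0.17 to 0.35, such as quantile normalization (0.21). Genes of the NRF2 response and glutathione lay inside the range (median -0.10, 15 genes), from Srxn1 (1.47) and Gsr (1.44) to catalase (Cat, -2.61).

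Known tubular injury markers of the kidney were higher in the liver (median 1.01, 10 genes, percentile 99.99), with 5 at least 2-fold higher (4 with dim signals raised). Lcn2 and Anxa2 (2.43) were the highest, whereas Havcr1, kidney injury molecule 1, had signals of 274.2 and 85.1, too dim for more than a bound of 1.07-fold lower. The 5 members in no other list had a median of 0.44, inside the random range. Kidney tubule markers themselves had a median of 0.01 over 11 genes, inside the range, with no member at least 2-fold higher or lower.

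Bile acid synthesis and hepatocyte transport were lower. Of 18 genes for bile acid synthesis and conjugation, 6 were at least 2-fold lower and none 2-fold higher (median -0.51, percentile 0.70). Cyp7a1 (-3.19) and Cyp8b1 (-2.73), which sets the share of cholic acid, were the lowest, and Baat (0.26) the highest. Without the members of other lists, the median was -0.32, inside the range. Of 19 hepatocyte transporters, 12 were at least 2-fold lower and none 2-fold higher (median -1.37, below all 10000 random lists). The bile salt export pump Abcb11 went from 7538 to 960.3 (-2.95), and Slco1b2 stood at -4.11. The highest was Slc22a5, a carnitine transporter, at 0.94.

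Drug metabolising cytochromes P450 had a median of -0.75 over 25 genes, with 10 at least 2-fold lower and none 2-fold higher, below all 10000 random lists. Cyp2j5 (-2.09) and Cyp2c37 (-2.09) were the lowest and Cyp2b10 (0.17) the highest. Phase II conjugation enzymes had a median of -0.92 over 24 genes, with 11 at least 2-fold lower and none 2-fold higher, also below all random lists, led by Gsta3 (-2.46), a glutathione S-transferase. Their highest member was Mgst1 (0.41).

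Lipid synthesis genes were lower in both lists that cover them. Of 20 genes of cholesterol synthesis and uptake, 12 were at least 2-fold lower and none 2-fold higher (median -1.25), with Idi1 (-3.15) and Insig1 (-1.92) lowest and Hsd17b7 (0.55) highest. The value of Hsd17b7 comes from a probe set that can cross-hybridise, and its 4 probe sets differed in sign. Of 26 genes of fatty acid and triglyceride synthesis, 15 were at least 2-fold lower and 3 at least 2-fold higher (median -1.08). Acss2 (-3.31) and the phosphatidate phosphatase Lpin1 (-2.67) were the lowest, whereas Cidec (at least 15.8-fold higher) and Insig2 (2.12) went the other way. Both medians lay below all 10000 random lists. By the probe set with the smallest difference, the fatty acid list stood at -0.46 (percentile 0.13). Fatty acid oxidation and ketogenesis lay inside the range (median -0.17, 28 genes), with 4 genes at least 2-fold higher and 4 at least 2-fold lower. Pdk4 (at least 49.2-fold higher) and the lipid droplet coat protein Plin2 (2.70) were its highest members and Cyp4a14 (-2.03) and Hadh (-1.83) its lowest. Lipoproteins and lipases had a median of 0.19 over 20 genes, inside the range, from Apoa4 (4.68) and Apoc2 (1.78) to Lipg (-1.41).

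The urea cycle and amino acid catabolism list had 15 of 32 genes at least 2-fold lower and none 2-fold higher, with a median of -0.95, below all 10000 random lists. Kynu (at least 8.37-fold lower), which cleaves kynurenine, and histidine ammonia-lyase (Hal, -2.67) were the lowest, and Mat1a (0.88) the highest. In nicotinamide and tryptophan metabolism, 9 of 13 genes were at least 2-fold lower (median -1.48, below all 10000 random lists). Nnmt, which methylates nicotinamide, was the highest, with signals of 2160 and 14221 (2.71), and Nampt stood at 0.22. Gluconeogenesis and glycogen genes had a median of -0.38 over 18 genes (percentile 3.08), inside the range but close to its limit. Of these 7 were at least 2-fold lower, including Ppp1r3b (at least 11.1-fold) and Slc2a2 (-3.72), and 1 was at least 2-fold higher, Igfbp1 (3.31). The list lay below the range in 7 of 15 alternatives, such as quantile normalization (-0.53). Glycolysis and hypoxia genes lay inside it (median -0.18, 22 genes), from Ldha (2.15) and Hif1a (1.66) to Pdk1 (-2.13), as did subunits of oxidative phosphorylation (median -0.22, 31 genes), from Cycs (0.58) to Ndufs1 (-1.59).

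Genes expressed more in male than in female liver were lower (median -1.03, 14 genes, below all 10000 random lists), with 8 at least 2-fold lower. Hsd3b5 (at least 21.2-fold lower) was the lowest and Mup3 (0.28) the highest. The value of Mup3 is uncertain, as its probe set can cross-hybridise and its 2 probe sets differed in sign. Female biased genes had a median of 0.10 over 9 genes, inside the range, from Sult1e1 (at least 18.5-fold higher) to Abcd2 (272.4 and 21.7, at least 1.07-fold lower). The growth hormone axis lay inside the range (median -0.28, 14 genes), with Igfbp1 (3.31) and Socs2 (2.29) highest and Stat5a (at least 1.93-fold lower) and Igfals (-2.05) lowest, and it was below the range by quantile normalization (-0.53). Core clock genes and their outputs had a median of -0.34 over 18 genes (percentile 2.68), just inside the range, and were below it in 4 alternatives, such as no filter on dim probe sets. Wee1 went from 1578 to 57.6 (at least 5.90-fold lower) and Dbp stood at -3.95, while Nfil3 (1.07) and Per1 (0.94) were higher.

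Hepatocyte genes of both zones of the liver lobule were lower. Periportal hepatocyte genes had a median of -0.68 over 18 genes (percentile 0.07), with Serpina12 (-2.76) lowest and Ctsc (0.84) highest. The median was -0.42 by the smallest difference and -1.38 without members of other lists, both below the range. Pericentral genes had a median of -1.03 over 19 genes, below all 10000 random lists, with the glutamate transporter Slc1a2 (at least 11.1-fold lower) and Aldh1a1 (-2.59) lowest and Axin2 (0.29) highest. Hepatocyte identity genes as a whole lay inside the range (median -0.20, 18 genes), from Prox1 (1.24, but -0.30 by another probe set) and Alb (0.73) to the bile acid receptor Nr1h4 (-1.59) and Cebpa (-1.24).

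Markers of other cell types moved apart. Pancreatic acinar markers were higher, with 10 of 14 at least 2-fold higher (8 with dim signals raised) and none 2-fold lower (median 1.58, above all 10000 random lists). Without probe sets with the suffix _x_at, _s_at or _a_at, the median was 1.03, still above the range. Cpa1, a pancreatic carboxypeptidase, went from 18.5 to 916.9 (at least 3.42-fold higher) and Ctrb1, chymotrypsinogen, from 115.6 to 1137.0 (at least 4.22-fold), while Cela1 (0.35) was the lowest. Cholangiocyte markers were higher, with 4 of 6 at least 2-fold higher, or 3 with dim signals raised (median 1.29, percentile 99.97), led by Epcam (at least 4.38-fold higher) and Krt19 (at least 1.93-fold). With no filter on dim probe sets, 12 cholangiocyte markers had a median of 0.42, inside the range. Kupffer cell and macrophage markers were lower (median -0.35, 22 genes, percentile 1.19), with C1qa lowest (at least 3.61-fold lower) and Cd68 highest (0.46). C1qa was read by 1 probe set, and C1qb (-0.18) and C1qc (-0.07) of the same list differed little. Sinusoidal endothelial markers were lower as well (median -0.50, 21 genes, percentile 0.25), with the dim Oit3 lowest (307.5 and 33.6, at least 1.20-fold lower). Lyve1, in contrast, went from 326.8 to 2741 (3.01). The macrophage list came inside the range without probe sets with these suffixes (-0.29). The endothelial list did so under stricter filters on dim probe sets (-0.30) and with signals under the array median raised to it (-0.26).

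Neutrophil markers had a median of 0.29 over 13 genes, inside the range, with S100a8 (45.6 to 1407, at least 5.21-fold higher) and Lcn2 highest and Cxcr2 (at least 1.14-fold lower) lowest. Other lists of cell types also lay inside the range. These were markers of monocytes (median 0.05, 8 genes), T and NK cells (0.05, 10 genes), B and plasma cells (-0.24, 14 genes), stellate cells and fibroblasts (-0.31, 16 genes), erythroid cells and platelets (-0.05, 10 genes), and adipose tissue, gallbladder or gut (0.11, 9 genes). Extracellular matrix genes had a median of 0.18 over 24 genes, inside the range, but lay above it with a stricter filter on dim probe sets (0.32). The basement membrane collagens Col4a1 (2.33) and Col4a2 (1.69) were its highest members, and Col3a1 (-0.64) and Tnc (at least 1.23-fold lower) its lowest.

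**Figure D3:**
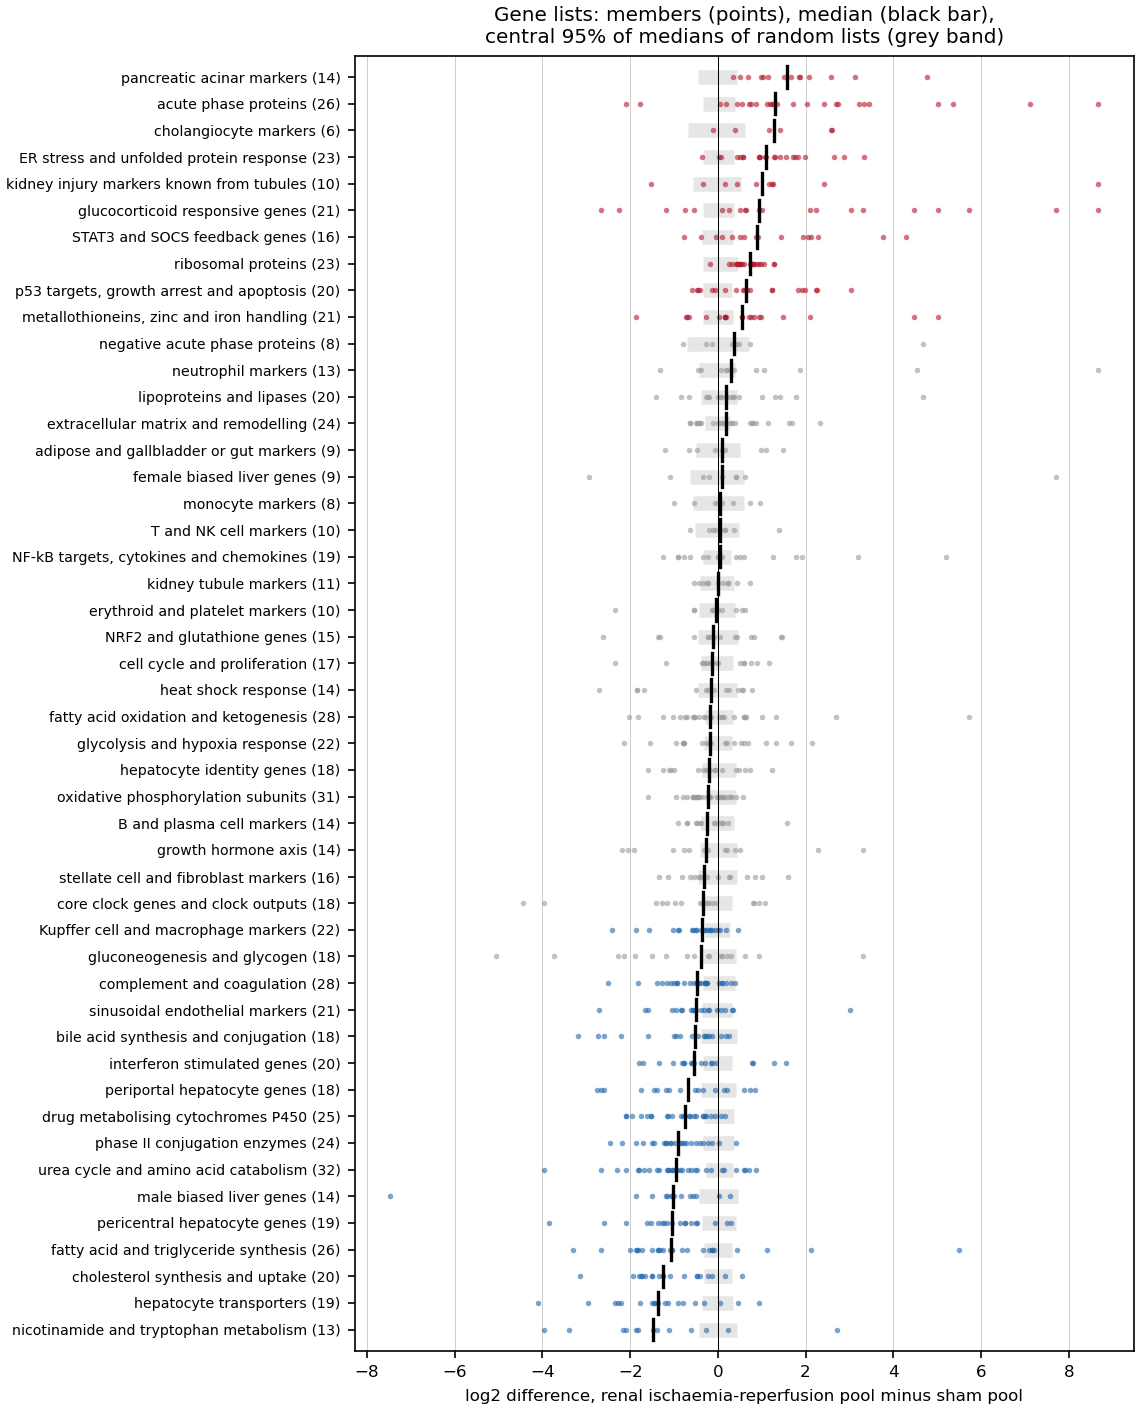
Log2 difference of the members of each gene list (points, renal ischaemia-reperfusion pool minus sham pool, 1 array each), the list median (black bar) and the central 95% of medians of random lists (grey band), with the number of genes in parentheses. Lists above the band are red and lists below it blue, from pancreatic acinar markers (1.58) at the top to nicotinamide and tryptophan metabolism (-1.48) at the bottom.

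Probe sets of the same gene disagreed with an SD of 0.72 on the log2 scale, and in 75.4% of the 771 genes with several probe sets and a difference of at least 2-fold, all probe sets had the same sign, against 55.3% of all 5028 genes with several probe sets past the filter. The lists share members, so their medians are not independent of each other.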

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

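The count over unnamed probe sets was chosen after the data were seen. Signals outside the main measurement that were higher in the renal ischaemia-reperfusion pool than in the sham pool are given here as values. The 18 probe sets for bacterial hybridisation controls had a median log2 difference of 0.28 (1.22-fold), and all 18 were higher. The control probe sets for mouse beta-actin had a median log2 difference of 1.11, with a signal of 16196 in the sham pool and 31292 in the renal ischaemia-reperfusion pool for the 3' set. Of 3849 probe sets unnamed here that passed the filter, 335 (8.70%) were at least 2-fold higher and 387 (10.1%) at least 2-fold lower.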

How the results depend on the processing

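The hybridisation-control reference, the filter on both arrays and signals raised to the array median were chosen after the data were seen. Of 25 lists outside the random range, 18 stayed outside on the same side in all alternatives that could be scored. Over all lists and alternatives, 685 of 714 values kept their side of the limits, 17 went outside and 12 came inside. Centring on the median and the hybridisation-control reference shift every gene alike, so list percentiles could not change under them. Their values are counted among the 685 all the same. Of 2516 values of the 202 genes the rule names, 2427 moved by less than the SD between probe sets, 79 moved by more, and 10 of genes with a 2-fold difference changed sign. A further 25 values of genes under 2-fold changed sign and are counted by the size of their move. Of these, 15 came with the hybridisation controls as the reference, such as Fgf21 (-0.20) and Igf1 (-0.07). That reference (-0.28) and centring on the median (0.01) shift every gene by less than the SD between probe sets (0.72). Values under these settings could therefore not move by more than that SD. Causes were not tested except where the setting itself gives them. Counts of higher and lower genes were 682 and 797 with the filter at the 75th percentile and 563 and 676 with both arrays at or above their medians, as fewer genes enter, and 721 and 864 with signals under the array median raised to it. They were 2449 and 2536 at 1.5-fold, 472 and 589 at 3-fold, and 756 and 2016 with the hybridisation controls as the reference. Lists with positive medians under 0.28, such as lipoproteins and extracellular matrix, turn negative with that reference, while percentiles do not move.

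Among lists that came inside, the metallothionein list was at 0.21 by quantile normalization, 0.18 by the probe set with the smallest difference, 0.35 without probe sets with the suffix _x_at, _s_at or _a_at (suffixed below) and 0.17 without members of other lists. Without members of other lists, bile acid genes stood at -0.32, glucocorticoid genes at 0.17 and kidney injury markers at 0.44. Kupffer cell markers stood at -0.29 without suffixed probe sets, endothelial markers at -0.30 under both stricter filters and -0.26 with dim signals raised to the array median, and cholangiocyte markers at 0.42 with no filter. Among lists that went outside, gluconeogenesis and glycogen stood at -0.46 after loess, -0.53 by quantile normalization, -0.38 with no filter and with unmatched random lists, -0.37 by the smallest difference, and -0.62 by the mean of probe sets and without members of other lists. Clock genes stood at -0.34 after loess and with no filter, at -0.28 by the smallest difference and at -0.30 with dim signals raised. The growth hormone axis stood at -0.53 by quantile normalization, -0.49 by the mean of probe sets and -0.67 without members of other lists. Heat shock genes stood at -0.65 by the mean of probe sets, matrix genes at 0.32 with the filter at the 75th percentile and neutrophil markers at 0.37 with no filter.

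Genes with a 2-fold difference that changed sign were Zbp1 (-0.27 by the mean of probe sets, -1.82 without suffixed ones), Me1 (0.11) and Mcm3 (-0.60), both by the smallest difference and without suffixed probe sets, Rpl35 (-0.80) without suffixed probe sets, Prox1 (-0.30) by the smallest difference and Pdgfra (-0.43 with no filter, -0.0069 with dim signals raised). The list of negative acute phase proteins was not scored without members of other lists, nor female biased genes and T and NK cell markers with the filter at the 75th percentile, nor cholangiocyte markers in 3 alternatives, as too few members were left. No paired analysis was possible because each group holds 1 array and the result comes from no test. Signals near or under the array median limit folds to lower bounds.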

Other observations

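The grouping of genes by the start of their symbols, and the tests of hepatocyte share, food intake and clock phase, were chosen after the results were seen. Groups of genes that share the start of their symbol were formed without regard to the fixed lists, but several of them hold members of those lists. Of 140 such groups with at least 10 genes, 13 had a median above the random range and 15 below it. By chance 7 would be outside if genes varied independently. Translation initiation factors (Eif) had a median log2 difference of 0.54 over 45 genes, 8 of them at least 2-fold higher and 1 at least 2-fold lower, above all 10000 random lists. Genes whose symbols start with Sec, many of which act in transport from the endoplasmic reticulum, stood at 0.48 over 26 genes, subunits of the proteasome cap (Psmd) at 0.54 over 14 genes and RNA helicases (Ddx) at 0.43 over 27 genes. Ribosomal proteins of the small (Rps, 0.70, 26 genes) and large subunit (Rpl, 0.58, 24 genes), which overlap a fixed list, were also higher. The other higher groups were Wfdc (0.52), Timm (0.44), Trmt (0.40), Med (0.39), Gtf (0.37), Polr (0.34) and Snx (0.24).

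Aldo-keto reductases (Akr) had the lowest median of the groups, -1.64 over 14 genes, with 9 at least 2-fold lower and none 2-fold higher. Aldehyde dehydrogenases (Aldh) stood at -1.18 over 17 genes, glucuronosyltransferases (Ugt) at -1.18 over 10 genes, the Car group, mostly carbonic anhydrases, at -0.99 over 12 genes and carboxylesterases (Ces) at -0.86 over 12 genes. All cytochromes P450 together had a median of -0.71 over 61 genes, with 22 at least 2-fold lower and 2 at least 2-fold higher. The Cyp, Ugt, Akr, Aldh and Car groups overlap fixed lists, as do the Hsd and Slc groups given next. The other lower groups were Abca (-0.85), Sema (-0.57), Abhd (-0.47), Hsd (-0.46), Prr (-0.45), olfactory receptors (Olfr, -0.31), Gpr (-0.27), Tmem (-0.15) and Slc (-0.11). Whether the groups share a function was not tested.

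Pancreatic acinar markers were higher in the renal ischaemia-reperfusion pool, and 2 technical explanations were weighed. Noise of dim probe sets picked by the filter was argued against, since the list stayed at a percentile of 100.0 with no filter. Pancreatic tissue in that pool and expression of these genes by liver cells after kidney injury could not be told apart. Another list of 26 acinar genes, named before its values were seen, had a median of 0.34 at a percentile of 97.93, past the limit set for pancreatic tissue. Of its genes, 6 were at least 2-fold higher and none 2-fold lower. With signals under the array median raised to it, chosen after the data were seen, 1 was at least 2-fold higher, and the median of 0.11 lay inside the range at a percentile of 84.5. At least Gnmt, Nr5a2 and Sel1l of that list are also expressed by liver, and 8 islet genes had a median of 0.15, inside the range. Of the islet genes, 2 were at least 2-fold higher and none 2-fold lower. They include Ttr, which also stands among the hepatocyte plasma protein genes, so this small list cannot decide on islet RNA. Among acinar markers chosen after their values were seen, Cela3b went from 918.7 to 2945 and Cela2a from 519.9 to 2244, whereas Cela1, the brightest in the sham pool, went from 1977 to 2531.

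The 8 lists of hepatic metabolism picked because they lay below the random range held 173 genes, 88 (50.9%) at least 2-fold lower and 4 (2.31%) at least 2-fold higher, against 9.59% and 8.71% of all genes. With fatty acid oxidation, lipoproteins, gluconeogenesis, glycolysis and oxidative phosphorylation, whose lists lay inside the range, 103 of 289 genes (35.6%) were at least 2-fold lower and 17 (5.88%) at least 2-fold higher. After a loess trend on signal was removed, 8 of the 8 lists still lay below the range. The random lists were already matched on signal and share such a trend, so this outcome was largely fixed in advance. It cannot decide on intensity dependent scaling. A lower share of hepatocyte RNA would raise markers of every other cell type alike if their mix and their expression stayed the same. A share lowered by 1 cell type alone, such as cholangiocytes, need not do so. The median over all these markers cannot decide on that. The expectation was set out after the lists of these markers had been seen, so it is no independent test. Markers of Kupffer (-0.35) and endothelial cells (-0.50) were lower and those of cholangiocytes higher (1.29). With stellate cell markers, all 65 had a median of -0.30, at a percentile of 0.13. These markers did not rise as a set, but they pool lists already known to be lower. A set of 27 hepatocyte plasma protein and identity genes had a median of 0.04, at a percentile of 51.93. Its 12 genes with a sham signal under 20000 had a median of -0.30, at a percentile of 8.55, also inside the range. The Kupffer and endothelial lists came inside the range in some alternatives, as did the cholangiocyte list with no filter (0.42), and a larger share of cholangiocyte RNA stays open. Reduced food intake could not be told apart from other effects of the kidney injury, since 27 genes induced by fasting stood at a percentile of 73.14 and went both ways, 6 at least 2-fold higher and 3 at least 2-fold lower. The kidney injury itself, which the design names, stays open as a biological hypothesis.

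Output genes of the clock such as Dbp and Wee1 were lower, and a different clock phase of the pools is a candidate explanation. Genes driven through E-box and D-box elements had a median of -0.84 over 11 genes (percentile 0.01). All 11 stand in the fixed clock list, which as a whole lay just inside the random range. They were grouped after its values were seen, so this percentile restates the low values of Dbp, Wee1 and others. Per1 of this group was higher (0.94). Genes driven through RORE elements, which peak at another phase, had one of 0.24 at a percentile of 71.85, inside the random range, but over 4 genes, under the minimum of 5. The difference of 1.08 lay at a percentile of 98.82 of random pairs, but it rests on the lower arm and on these 4 genes, so a shift in phase and a weaker clock output cannot be told apart. The time of day of sampling is not given in the sources used here.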
